A study of Homo sapiens with 6 samples.

How the data were processed

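Human HEK293A-GNB1L-dTAG cells were grown for 3 days with 1 µM dTAG-NEG or 1 µM dTAGv-1, and 3 RNA libraries were sequenced per compound. RNA was extracted with a Qiagen kit and libraries were made with an NEB mRNA kit, per the labels' protocols. Per the submitters' processing notes, Trimmomatic, HISAT2 and HTSeq were used with the GRCh38 (hg38) genome, in an order and with versions, gene annotation and strand setting not given in the sources used here. The authors deposited a table of whole-number counts per gene and a table of FPKM values, each with 69215 gene rows and 6 columns. Column names were matched to samples by compound letters and replicate number. The last line of each count column is a total, which equals the sum of the other lines and was left out. Some 9053 rows share a symbol with another row, and they held 0.541% to 0.575% of counts per library. They were kept apart, and the rows of LDHA, ACACA, LSS, SESN2, HSPA1A, IER3 and GPI are uncertain for that reason.

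How the FPKM values were made is not given in the sources used here. The length that the deposited counts and FPKM imply is 1 number per row, but across 11658 rows with a mean of at least 100 counts it was unrelated to the annotated exon length (Spearman's rho = 0.00806 across genes). For ATM it is 106 nt against 23972 nt. The FPKM values were therefore used to compare a gene between libraries and never to compare genes. The implied length still bears on which rows pass the FPKM filter and on how far the pseudocount shrinks a fold.

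Total counts were 29972400, 28997536, 30026498 in the dTAG-NEG libraries 1, 2 and 3 and 24010127, 26187754, 22885466 in the dTAGv-1 libraries 1, 2 and 3. A count of 3 corresponds to 0.0999 to 0.131 CPM (counts scaled to library size). The counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter, which kept 17713 rows, robust quasi-likelihood fits and two-sided F tests of dTAGv-1 against dTAG-NEG with no replicate block, adjusted by Benjamini and Hochberg over all genes tested. The threshold was an adjusted p of 0.05, and a change of at least 2-fold is a description after the test. The biological coefficient of variation was 0.0874. SE is the size of the log2 fold change over the root of F, and intervals are 95%. A gene is said to rise, fall or change where it passed this test, values in parentheses after a gene are its log2 fold change ± SE over 3 libraries per compound, and levels are mean TMM-scaled CPM ± SD. No pair of libraries of a group looked like a duplicate, since their counts differed by 3.84 to 13.1 times the sampling noise (chi-square per degree of freedom).

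Before the data were examined, 34 gene lists were fixed: PIKK kinases, TTT, R2TP and HSP90 co-chaperones, PIKK partners, p53 targets, ATF4 and amino acid response, NMD factors, NMD substrates, sterol synthesis, fatty acid synthesis, lysosome and autophagy, hypoxia and VHL-HIF targets, glycolysis, oxidative phosphorylation nuclear, mitochondrially encoded, DNA replication S phase, mitosis, replication-dependent histones. The others were Fanconi and homologous recombination, cytosolic ribosomal proteins, ribosome biogenesis and MYC targets, heat shock response, ER unfolded protein response, interferon response, NRF2 targets, immediate early genes, TGF-beta and matrix, neuronal genes expressed in HEK293, senescence-secreted factors, fibroblast markers, leukocyte and blood markers, squamous epithelial markers, hepatocyte and endothelial markers, nuclear-retained RNA and 22q11.2 neighbours of GNB1L. Members were matched by symbol, older symbols through the reference's table, and members without a row were not analysed here. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it (limma 3.58.1), adjusted over the 31 lists. Camera compares a list with the other genes, while fry asks whether a list's genes move one way on balance. A call lost with the estimated correlation need not mean that the members are correlated. Among lists that lost their call, the estimate was above the preset 0.01 for some, such as glycolysis (0.252). It was below 0.01 for others, such as sterol synthesis (0.00138), DNA replication (0.00294), NRF2 targets (-0.0178) and senescence-secreted factors (-0.0542). The rule for named genes, also fixed then, took GNB1L, the 6 kinases, the 12 highest and 12 lowest log2 fold changes among genes past the threshold with a mean of at least 5 CPM and groups that do not overlap, and up to 4 members past the threshold per list with the largest changes, or up to 2 of the highest mean where none passed. Some genes are not reported here, and the others numbered 142, of which 133 passed. PLK2, ELOVL5 and other list members outside this rule, named because few members moved that way, were chosen after their values were seen.

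Gene positions, transcript lengths, GC content and overlaps come from GENCODE 29 on GRCh38, matched by symbol, with 61919 rows matched to 1 gene. Counts are less certain where exons overlap those of another gene, as for FADS1 and FADS2 or FAS and ACTA2, and for ribosomal protein genes, which have many pseudogenes. Length and GC were known for 96.9% of genes tested. Fixed alternatives were median-of-ratios scaling, no scaling beyond library size, no filter on low counts or a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, and limma on log2(FPKM + 1) with a mean FPKM of at least 0.5, with a pseudocount of 0.1 or with no filter. Added after seeing the data were smooths of each library on transcript length or GC content (span 0.3), summed rows of one symbol, and leaving out replicate 2 of both compounds.

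The steps were tested on simulated data. Of 200 genes changed among 17713 simulated from the means and spread of this comparison, edgeR recovered 40.0% at 1.25-fold, 70.0% at 1.5-fold, 80.0% at 2-fold and 88% at 3-fold. It called 159 genes, 20 of them unchanged, or 12.6% of calls, a larger share than the 5% that the threshold of 0.05 aims at, and 4.66% of unchanged genes had an unadjusted p under 0.05. The recovery and the false share depend on how many genes change. With 200 changed genes in the simulation and 6475 past the threshold in the data, these shares do not carry over to the data. A simulated length trend with no gene changed gave 414 calls, and 6 after the smooth. The simulated trend ran mainly between the compounds. In the data the median log2 fold change was -0.0626 for transcripts up to 1490 nt and -0.0324 for those of at least 6981 nt. The long ones lay at -0.114 and 0.0845 from the group mean in dTAG-NEG replicates 2 and 3. The simulation therefore says little on how the smooth acts on a trend within a group. Camera called 20 of 20 changed sets and 0 of 20 unchanged sets. The simulated genes were drawn independently of each other. In the real lists the estimated correlation was up to 0.968, for the PIKK kinases, with 0.753 for cytosolic ribosomal proteins and 0.703 for mitochondrially encoded genes. The simulation therefore does not show how camera at the preset correlation behaves on correlated lists.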

Results

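RNA was sequenced from HEK293A-GNB1L-dTAG cells, a human embryonic kidney line in which GNB1L carries a degradation tag. GNB1L is a WD40-repeat protein encoded on chromosome 22. A dTAG compound binds the tag, and a degrader such as dTAGv-1 also recruits the ubiquitin ligase VHL, so that the tagged protein is destroyed. With dTAG-NEG, the control compound, the tagged protein stayed at a clearly higher level, according to the submitters' design text. Cells received either compound at 1 µM for 3 days, and 3 libraries were made per compound. Total counts per library ran from 22885466 to 30026498 over 69215 gene rows, of which 17713 were tested. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Cells without the tag were not analysed here, so the comparison does not separate loss of GNB1L from other effects of dTAGv-1.

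The question stated for the series was whether depletion of GNB1L changes the mRNA of the PIKK family, the large kinases of DNA damage signalling, growth control and RNA surveillance. The 6 members went different ways with dTAGv-1. SMG1, the kinase that phosphorylates UPF1 in nonsense-mediated mRNA decay (NMD), rose 1.59-fold, from 237 ± 44.5 to 377 ± 31.2 CPM (SD, n = 3 libraries each). ATM, the kinase that responds to DNA double-strand breaks, fell 1.30-fold, from 83.6 ± 12.1 to 64.4 ± 5.21 CPM. PRKDC, the catalytic subunit of DNA-PK, stood at 1155 ± 163 CPM with dTAG-NEG and 931 ± 59.9 CPM with dTAGv-1 and missed the threshold. MTOR, ATR and TRRAP, the growth kinase, the replication stress kinase and a scaffold of histone acetyltransferases, differed by at most 1.13-fold and did not pass.

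GNB1L mRNA itself, encoded at chromosome 22, 19783224 to 19854939 (GRCh38), was measured at 8.76 ± 0.520 CPM with dTAG-NEG and 10.3 ± 1.21 CPM with dTAGv-1. Its log2 fold change was 0.23 ± 0.123 (SE), with an edgeR adjusted p of 0.162, and the 95% interval ran from -0.03 to 0.49. The degrader acts on the protein, so this mRNA does not check the labels. Among the kinases the edgeR quasi-likelihood test gave log2 fold changes of 0.67 ± 0.161 for SMG1 (adjusted p = 0.0302), -0.38 ± 0.103 for ATM (adjusted p = 0.0170) and -0.31 ± 0.104 for PRKDC (adjusted p = 0.0543). The edgeR values were 0.18 ± 0.0724 for TRRAP (adjusted p = 0.0692), 0.13 ± 0.0641 for MTOR (adjusted p = 0.132) and -0.06 ± 0.0834 for ATR (adjusted p = 0.621). The 95% interval of the fold was 1.19 to 2.13 for SMG1, 0.656 to 0.904 for ATM, 0.679 to 0.956 for PRKDC and 0.847 to 1.09 for ATR. It was 0.995 to 1.20 for MTOR and 1.02 to 1.26 for TRRAP. Thus 2 of 6 kinase mRNAs passed over all genes tested, and 4 of 6 passed adjusted over the list alone, with PRKDC lower (edgeR adjusted p = 0.0405) and TRRAP higher (edgeR adjusted p = 0.0411). Camera did not call the kinases as a group (camera adjusted p = 0.929, median log2 fold change 0.03). Camera looks for a shift in 1 direction, so it does not show whether members moved opposite ways. Fry's form for changes in either direction called the kinases (fry adjusted p = 3.54e-05). It also called most other lists, so it does not single them out.

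The SMG1 libraries of the 2 compounds did not overlap, while ATM stood at 69.8 CPM in dTAG-NEG replicate 2 and 69.9 CPM in dTAGv-1 replicate 2. Single libraries decided several calls. SMG1 missed the threshold without dTAG-NEG replicate 1 (edgeR adjusted p = 0.0612), dTAGv-1 replicate 2 (0.0730) or dTAGv-1 replicate 3 (0.0544), with log2 fold changes of 0.69, 0.60 and 0.70, and on FPKM values ATM missed it (limma adjusted p = 0.0825). Over all alternatives the adjusted p ran from 5.06e-07 to 0.0730 for SMG1, the lowest at its smallest log2 fold change of 0.46 without both replicates 2, and from 3.09e-08 to 0.224 for ATM. PRKDC passed without dTAG-NEG replicate 2 (edgeR adjusted p = 2.89e-06) or dTAGv-1 replicate 2 (0.0244). With all libraries it passed with median-of-ratios scaling (edgeR adjusted p = 0.0372), at 1 CPM (0.0366), with no filter (1.20e-06) and in DESeq2 (adjusted p = 0.0434). It missed with library size only (edgeR adjusted p = 0.0934) and in limma-voom (adjusted p = 0.102). Its adjusted p ran from 4.56e-08 to 0.288. Of the 20 alternatives PRKDC passed in 10, TRRAP in 5 and MTOR in 3. MTOR and TRRAP passed without dTAG-NEG replicate 3 (edgeR adjusted p = 0.0414 and 0.0243), while without dTAG-NEG replicate 2 their log2 fold changes were 0.07 and 0.10. Over all alternatives their adjusted p ran from 0.00358 to 0.901 for MTOR and from 2.55e-05 to 0.543 for TRRAP. Both were lowest with the length smooth, added after seeing the data. There MTOR was at 0.16 ± 0.0413, TRRAP at 0.24 ± 0.0365 and PRKDC at -0.25 ± 0.0396 (edgeR adjusted p = 4.09e-05 for PRKDC). The number of kinases past the threshold was 1, 3 and 4 without dTAG-NEG replicate 1, 2 and 3, and 2, 2 and 1 without dTAGv-1 replicate 1, 2 and 3. It was 4 without both replicates 2, chosen after seeing the data, where ATR was also lower at -0.23 (edgeR adjusted p = 0.00698, up to 0.958 elsewhere). All 6 transcripts are long, at 8249 to 16115 nt, and the 1623 genes with transcripts of at least 6981 nt lay at a median log2 of -0.11 from the group mean in dTAG-NEG replicate 2, 0.0336 in replicate 1 and 0.0845 in replicate 3. In dTAGv-1 replicates 1, 2 and 3 that median was -0.0295, 0.0593 and -0.0292. Exons of SMG1, ATM, ATR, MTOR, TRRAP and GNB1L overlap those of other annotated genes, and the strand setting of the counting is not given in the sources used here, so their counts may hold some reads of a neighbour.

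**Figure D1:**
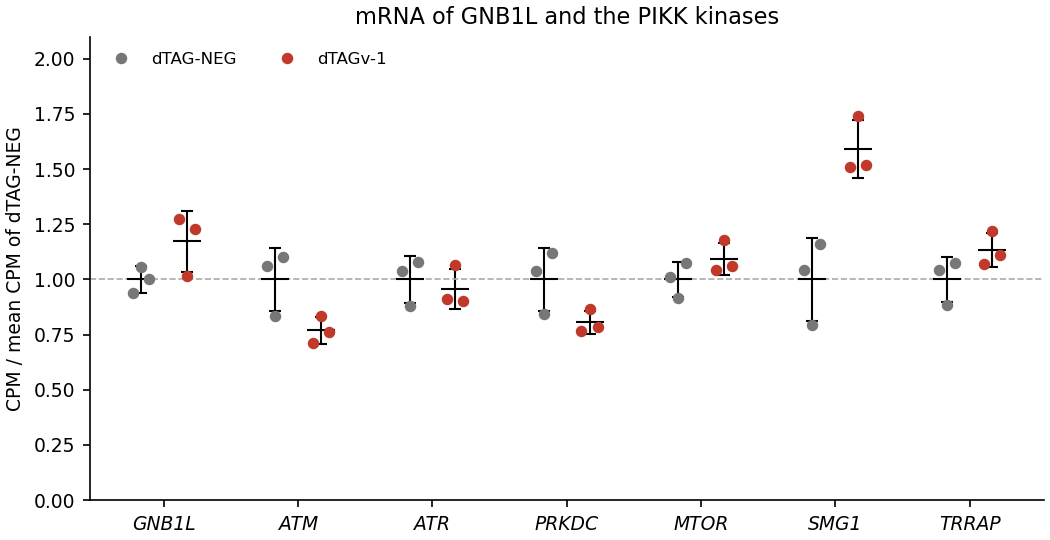
TMM-scaled CPM of GNB1L and the 6 PIKK kinases, divided by the gene's mean CPM with dTAG-NEG (linear axis from 0), one point per library, grey for dTAG-NEG and red for dTAGv-1 (n = 3 each), with bars for mean and SD. SMG1, with mean levels of 237 CPM with dTAG-NEG and 377 CPM with dTAGv-1, is the one gene of the 7 whose groups do not overlap.

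Across the transcriptome the 2 compounds gave distinct profiles. MYC, a growth-promoting transcription factor, rose 6.32-fold with dTAGv-1, from 29.8 ± 2.28 to 188 ± 2.36 CPM (SD, n = 3 libraries each). GADD45B, a stress-inducible growth arrest gene, rose 7.14-fold, from 51.6 ± 4.62 to 368 ± 13.6 CPM, and ANKRD1, a transcriptional target of YAP, rose 9.64-fold, from 29.1 ± 2.75 to 281 ± 22.2 CPM. The chemokine genes CXCL8 and CCL20 rose 14.2-fold and 15.5-fold from low levels, CXCL8 from 2.15 ± 0.277 to 30.6 ± 1.02 CPM. In the other direction MAP2K6, an activator of p38 kinases, fell 40.4-fold, from 12.8 ± 0.334 to 0.315 ± 0.110 CPM, COL3A1, a fibrillar collagen gene, fell 17.2-fold, and MYO6, an unconventional myosin, fell 3.57-fold, from 125 ± 8.37 to 35.0 ± 1.26 CPM. The log2 fold changes (SE) were 2.66 ± 0.0628 for MYC, 2.84 ± 0.0644 for GADD45B, 3.27 ± 0.0762 for ANKRD1, 3.83 ± 0.109 for CXCL8, 3.95 ± 0.236 for CCL20, -5.34 ± 0.211 for MAP2K6, -4.10 ± 0.206 for COL3A1 and -1.83 ± 0.0646 for MYO6.

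By the naming rule fixed in advance, the 12 genes with the highest log2 fold change also held ACTBL2 (3.36 ± 0.110, SE), the long non-coding RNA LINC01411 (3.33 ± 0.127), ETV5 (3.20 ± 0.165), CPA4 (2.96 ± 0.212), C11orf96 (2.83 ± 0.170), GADD45G (2.66 ± 0.119) and PTX3 (2.31 ± 0.109). ETV5 encodes an ETS transcription factor and PTX3 a secreted pentraxin. The 12 lowest also held IGFBP5 (-3.04 ± 0.177), METTL7A (-3.02 ± 0.143), IFIT1 (-2.84 ± 0.189), BST2 (-2.00 ± 0.202), CDH1 (-1.86 ± 0.159), PCDH18 (-1.85 ± 0.153), SIX2 (-1.72 ± 0.218), MRC2 (-1.71 ± 0.0801) and LRP2 (-1.70 ± 0.132). IFIT1 and BST2 are interferon-inducible, CDH1 encodes E-cadherin, SIX2 is a nephron progenitor transcription factor and LRP2 encodes megalin, a receptor of the kidney tubule. In these genes the largest edgeR adjusted p was 1.60e-05. MYC lies at chromosome 8, 127735434 to 127741434, CXCL8 at chromosome 4, 73740506 to 73743716, MAP2K6 at chromosome 17, 69414698 to 69553861 and COL3A1 at chromosome 2, 188974320 to 189012746 (GRCh38). ETV5, C11orf96, PTX3, COL3A1, IGFBP5, CDH1 and MRC2 share exon positions with another annotated gene and are the less certain of the set.

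In total 6475 of 17713 genes passed an edgeR adjusted p of 0.05, 3214 higher and 3261 lower with dTAGv-1. The deposited FPKM values, which have no TMM scaling, gave in limma 3155 higher and 2125 lower, or 59.8% higher against 49.6%. Most changes were small, since 4323 of the genes past the threshold changed by less than 1.5-fold and 966 by at least 2-fold, 434 higher and 532 lower. The balance of directions depends on the scaling: with library size only 3799 rose and 2686 fell, 487 and 479 at 2-fold, and on FPKM 209 rose and 205 fell at 2-fold. The groups did not overlap in 8350 of the 17713 genes tested, where chance separates 3 against 3 libraries in 10% of genes. Libraries of one compound correlated across genes at 0.988 to 0.989 and libraries of different compounds at 0.975 to 0.977 (Pearson's r of log2 CPM, genes are not independent replicates). The first principal component held 50.3% of the variance and parted the compounds, and replicate 2 of each compound lay farthest out on the second, which held 13.7%. Without both replicates 2, 6134 genes passed and 1013 by at least 2-fold. Terms of the gene ontology were not analysed here.

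**Figure D2:**
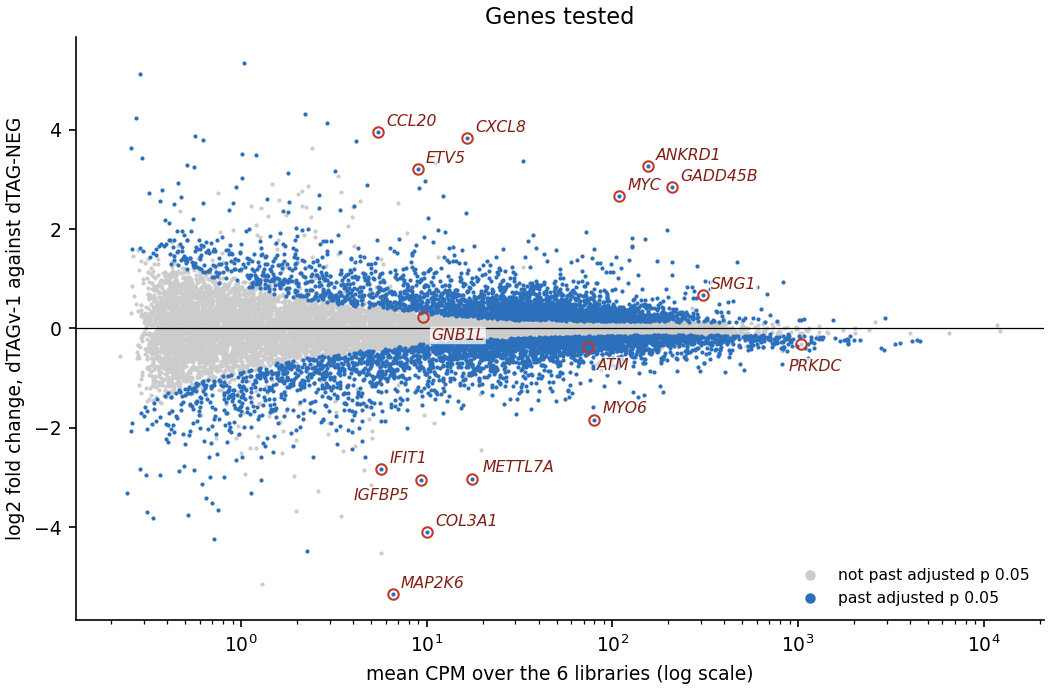
Log2 fold change, dTAGv-1 against dTAG-NEG, against the mean CPM over the 6 libraries (log scale) for the genes tested, XIST and Y-linked genes left out, with blue points past an edgeR adjusted p of 0.05 and red circles around genes named in the text. MYC, ANKRD1 and GADD45B stand out among well expressed genes at 2.66, 3.27 and 2.84, and MAP2K6 is the lowest of the circled genes at -5.34.

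Genes that act with the PIKK family were described in fixed lists. Factors of NMD, the decay of mRNAs with premature stop codons, were higher as a group with dTAGv-1: 8 of 17 rose, 3 fell and 6 did not pass (10 higher and 3 lower adjusted over the list alone). SMG9, a partner of SMG1, rose by 1.31 ± 0.0539 on the log2 scale (SE), SMG5 by 0.72 ± 0.0479, UPF3B by 0.66 ± 0.0512 and UPF2 by 0.60 ± 0.0600. The members that fell were RNPS1 (-0.21 ± 0.0491), EIF4A3 (-0.19 ± 0.0502) and PNRC2 (-0.18 ± 0.0521). Of 30 transcripts known as NMD substrates, 20 rose, 3 fell and 7 did not pass (20 higher and 3 lower adjusted over the list alone), with a median log2 fold change of 0.64. GADD45B, UPP1 (1.57 ± 0.0694), EPB41L4A-AS1 (1.62 ± 0.0887) and ARC (1.39 ± 0.136) rose the most, GADD45B and ARC being inducible by stress or activity as well, and SRSF2 (-0.27 ± 0.0567), SRSF3 (-0.16 ± 0.0524) and HNRNPDL (-0.15 ± 0.0451) fell. UPF3B and SMG5 stand in both lists. Camera called the factors higher (camera adjusted p = 2.90e-06, and adjusted p = 0.0363 with an estimated correlation) and the substrates higher (camera adjusted p = 5.07e-30, but adjusted p = 0.0543 with an estimated correlation).

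The TTT, R2TP and HSP90 co-chaperones, which fold and assemble PIKK proteins, had 4 of 16 members higher and 12 not past (4 higher adjusted over the list alone). PDRG1, a prefoldin-like subunit, rose from 42.4 ± 0.0501 to 112 ± 6.73 CPM, and URI1 (0.41 ± 0.0468), PIH1D1 (0.28 ± 0.0598) and the TTT subunit TTI1 (0.26 ± 0.0642) rose by less. Camera called the list higher (camera adjusted p = 0.0248, but adjusted p = 0.346 with an estimated correlation), and it missed without dTAG-NEG replicate 3 (adjusted p = 0.0797). Of 26 PIKK partners, the subunits, activators and substrates of the kinases, 5 rose and 5 fell (6 higher and 5 lower adjusted over the list alone), and camera did not call the list (adjusted p = 0.269). SMG9, the nuclease gene DCLRE1C (0.67 ± 0.0810) and the DNA ligase gene LIG4 (0.38 ± 0.0771) rose, while DEPTOR, an inhibitor of mTOR, fell (-0.90 ± 0.209). XRCC4 (0.28 ± 0.0763) and MRE11 (0.23 ± 0.0532) also rose, and CHEK2 (-0.33 ± 0.0622), AKT1S1 (-0.20 ± 0.0566), XRCC5 (-0.19 ± 0.0452) and KAT2A (-0.16 ± 0.0559) also fell. The partners' median log2 fold change was -0.03, against a mean of 0.02 and a camera direction of higher, and fry called them higher (fry adjusted p = 0.00651). Of 11 tested neighbours of GNB1L at 22q11.2, 4 rose and 7 did not pass (4 higher adjusted over the list alone), led by HIRA (0.48 ± 0.0807) and TXNRD2 (0.48 ± 0.0763), and camera did not call the list (adjusted p = 0.214) except as higher with the GC smooth (adjusted p = 0.0397).

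Targets of p53 fell together with dTAGv-1. Of 28 members, 23 fell, 1 rose and 4 did not pass (1 higher and 23 lower adjusted over the list alone). DDB2, a nucleotide excision repair gene, fell from 81.3 ± 3.99 to 37.0 ± 2.35 CPM, FDXR from 45.6 ± 6.31 to 19.0 ± 1.14 CPM, and the death receptor genes FAS and EDA2R had log2 fold changes of -0.93 ± 0.0816 and -1.15 ± 0.0796 (SE). The kinase gene PLK2 was the member that rose (0.81 ± 0.0695). Mitotic genes fell as well, 26 of 30 members (1 higher and 28 lower adjusted over the list alone), among them CDC20 (-0.86 ± 0.0596), MKI67 (-0.72 ± 0.115), KIF20A (-0.67 ± 0.0540) and TOP2A (-0.64 ± 0.0512). Camera called both lists lower, the p53 targets (camera adjusted p = 1.94e-17, and adjusted p = 0.0363 with an estimated correlation) and the mitotic genes (camera adjusted p = 7.27e-14, and adjusted p = 0.0363 with an estimated correlation).

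Of 35 DNA replication genes 14 fell, 2 rose and 19 did not pass (2 higher and 14 lower adjusted over the list alone). UHRF1 (-0.49 ± 0.0512), TK1 (-0.47 ± 0.0652), MCM5 (-0.47 ± 0.0515) and CDT1 (-0.39 ± 0.0653) fell, and GINS3 (0.35 ± 0.0636) and GINS4 (0.32 ± 0.0557) rose. Camera called the list lower (camera adjusted p = 0.0178, but adjusted p = 0.131 with an estimated correlation). Of 22 Fanconi and homologous recombination genes, 5 rose and 2 fell (5 higher and 2 lower adjusted over the list alone), and camera did not call them (adjusted p = 0.274). FANCI (0.33 ± 0.0522), PALB2 (0.33 ± 0.0798), XRCC3 (0.29 ± 0.0730), BRCA1 (0.25 ± 0.0574) and FANCC (0.17 ± 0.0530) rose, and FANCG (-0.19 ± 0.0643) and FANCA (-0.17 ± 0.0588) fell. Of 13 replication-dependent histone genes, 0 passed in edgeR (0 adjusted over the list alone), with 2 below an unadjusted p of 0.05 in edgeR, and DESeq2 and limma-voom called 0 and 0. With the length smooth 2 histone genes rose, and 1 rose without both replicates 2. H2BC12 stood at 22.8 ± 1.83 CPM with dTAG-NEG and 20.8 ± 1.95 CPM with dTAGv-1, and H1-2 at 15.5 ± 0.153 CPM with dTAG-NEG and 14.8 ± 2.49 CPM with dTAGv-1. The histone list had a median log2 fold change of -0.06, a mean of 0.0618 and a camera adjusted p of 0.929.

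Of the lists of lipid and sugar metabolism, camera called fatty acid synthesis, sterol synthesis and glycolysis lower with dTAGv-1. With an estimated correlation it kept the call of fatty acid synthesis (adjusted p = 0.0363) but not of sterol synthesis (adjusted p = 0.112) or glycolysis (adjusted p = 0.178). The estimate was 0.252 for glycolysis but 0.00138 for sterol synthesis, so correlated members do not account for the lost sterol call. In fatty acid synthesis 9 of 11 members fell and 1 rose (1 higher and 9 lower adjusted over the list alone). The desaturase genes FADS2 and FADS1 fell, FADS2 from 184 ± 7.42 to 75.5 ± 1.74 CPM, and FASN, the fatty acid synthase gene, fell from 653 ± 44.6 to 369 ± 1.66 CPM. The elongase gene ELOVL5 rose (0.23 ± 0.0532). In sterol synthesis 11 of 25 fell and 2 rose (2 higher and 13 lower adjusted over the list alone), with TM7SF2 (-0.83 ± 0.0682) and ACAT2 (-0.65 ± 0.0600) lower and HMGCS1 (0.56 ± 0.0469) and INSIG1 (0.53 ± 0.0494) higher. In glycolysis 13 of 18 fell and 2 rose (2 higher and 13 lower adjusted over the list alone). PKM, the pyruvate kinase gene, fell from 1316 ± 25.2 to 848 ± 24.5 CPM, PGAM1 (-0.62 ± 0.0482) and ENO2 (-0.51 ± 0.0637) fell too, and SLC2A3 (0.49 ± 0.0556) and PFKFB3 (0.25 ± 0.0723) rose. With the preset correlation the camera adjusted p was 8.86e-11 for fatty acid synthesis, 0.00793 for sterol synthesis and 5.00e-06 for glycolysis.

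Nuclear genes of oxidative phosphorylation had 10 of 29 members lower and 19 not past (10 lower adjusted over the list alone), among them NDUFB10 (-0.60 ± 0.0596), ATP5MC1 (-0.46 ± 0.0712), CYC1 (-0.43 ± 0.0682) and ATP5F1B (-0.35 ± 0.0458). Of 13 mitochondrially encoded mRNAs 9 fell and 4 did not pass (10 lower adjusted over the list alone), MT-ND5 from 3316 ± 171 to 2464 ± 164 CPM and MT-ND6 from 818 ± 52.3 to 632 ± 23.2 CPM. Mitochondrial rows held 5.45% to 5.86% of counts with dTAG-NEG and 5.14% to 5.55% with dTAGv-1. Camera called the nuclear list lower (camera adjusted p = 0.0107, but adjusted p = 0.569 with an estimated correlation), but not without dTAG-NEG replicate 2 (adjusted p = 0.0978) or without both replicates 2 (adjusted p = 0.353). Without both replicates 2, 4 members rose and 7 fell, with a median log2 fold change of -0.03 against -0.13, and with the length smooth 2 rose and 12 fell. Camera called the mitochondrial list lower (camera adjusted p = 0.000511, but adjusted p = 0.390 with an estimated correlation), but not with the length smooth (adjusted p = 0.0603). Of 31 lysosome and autophagy genes 11 rose and 3 fell (11 higher and 3 lower adjusted over the list alone), with FLCN (0.47 ± 0.0839) and WIPI1 (0.45 ± 0.0966) higher and ASAH1 (-0.40 ± 0.0715), CTSA (-0.27 ± 0.0611) and ATP6AP1 (-0.17 ± 0.0552) lower, and camera did not call the list (adjusted p = 0.157). Targets of hypoxia and the VHL-HIF pathway, the pathway of the ligase that dTAGv-1 recruits, went both ways: 3 of 19 rose and 8 fell (3 higher and 8 lower adjusted over the list alone). CA12 (-1.65 ± 0.138), EGLN3 (-1.26 ± 0.119), PFKFB4 (-0.96 ± 0.185) and LOX (-0.96 ± 0.139) fell, and NDRG1 (0.92 ± 0.0618), ADM (0.87 ± 0.0784) and VEGFA (0.31 ± 0.0590) rose. Their median log2 fold change was 0.0134 and their mean -0.21, and camera gave a lower direction that did not pass (adjusted p = 0.412).

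Immediate early genes, the first to respond to growth and stress signals, were higher with dTAGv-1. Of 20 members 15 rose and 5 did not pass (15 higher adjusted over the list alone). CCN2, a target of YAP signalling, rose from 56.0 ± 3.65 to 198 ± 7.57 CPM, EGR1 from 5.18 ± 0.302 to 19.9 ± 1.23 CPM, and FOS (2.01 ± 0.264) and FOSB (1.76 ± 0.229) rose from 0.910 ± 0.302 and 1.31 ± 0.254 CPM. The senescence list, which holds secreted factors and intracellular markers, had 7 of 13 members higher and 5 lower (7 higher and 5 lower adjusted over the list alone). The chemokine genes CXCL8, CXCL2 (4.13 ± 0.252) and CCL20 rose, and IGFBP5, LMNB1 (-0.69 ± 0.0455), HMGB2 (-0.41 ± 0.0529), CDKN2A (-0.26 ± 0.0801) and IGFBP7 (-0.22 ± 0.0692) fell. Loss of LMNB1 and HMGB2 marks senescence, while CDKN2A is a marker that rises in it, so the list mixes members expected to move opposite ways. Camera called the early genes higher (camera adjusted p = 5.27e-23, and adjusted p = 0.0363 with an estimated correlation) and the senescence list higher (camera adjusted p = 0.00456, but adjusted p = 0.112 with an estimated correlation).

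The ATF4 and amino acid response split. Of 38 members 10 rose and 12 fell (10 higher and 13 lower adjusted over the list alone): the stress genes ATF3 (1.63 ± 0.0540) and PPP1R15A (1.79 ± 0.0550) rose, and DDIT4, a negative regulator of mTORC1, fell from 55.0 ± 4.36 to 18.0 ± 2.03 CPM. The list's median log2 fold change was -0.0582 and its mean 0.0495, and camera did not call it (adjusted p = 0.0919). Camera called it higher without dTAG-NEG replicate 2 (adjusted p = 0.0339), without both replicates 2 (0.0361) or with no filter (0.0287). Of 20 genes of the ER unfolded protein response 10 rose and 4 fell (10 higher and 4 lower adjusted over the list alone), with DNAJB9 (0.83 ± 0.0724) and ERN1 (0.62 ± 0.0871) higher and CALR (-0.38 ± 0.0464) lower, and camera did not call it (adjusted p = 0.0840) except as higher with library size only (adjusted p = 0.0472) or no filter (0.0162). In the heat shock response 8 of 19 fell and 2 rose (2 higher and 10 lower adjusted over the list alone). HSPB1 fell from 198 ± 19.3 to 76.7 ± 5.23 CPM, HSPA4L (-0.45 ± 0.0657) and HSPA8 (-0.36 ± 0.0478) fell, and HSPH1 (0.24 ± 0.0489) rose along with a row of HSPA1A, a symbol that occurs in 5 gene rows and is uncertain. Of 17 NRF2 targets 11 fell and 2 rose (3 higher and 12 lower adjusted over the list alone), with AKR1C1 (-2.30 ± 0.443) and AKR1C2 (-1.64 ± 0.346), near-identical paralogs whose reads cannot be parted with certainty, and NQO1 (-0.59 ± 0.179) lower and OSGIN1 (1.76 ± 0.295) higher. Of 17 interferon response genes 6 fell and 2 rose (2 higher and 6 lower adjusted over the list alone). IFIT1 fell from 9.92 ± 1.67 to 1.38 ± 0.216 CPM, BST2, IFIT2 (-1.72 ± 0.370) and IFIH1 (-1.13 ± 0.179) fell, and MX1 (0.97 ± 0.209) and IRF1 (0.41 ± 0.126) rose.

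Of these stress lists, camera called heat shock lower (camera adjusted p = 0.0138, but adjusted p = 0.371 with an estimated correlation) and NRF2 targets lower (camera adjusted p = 0.0143, but adjusted p = 0.131 with an estimated correlation). It called the interferon list lower (camera adjusted p = 0.0393, but adjusted p = 0.172 with an estimated correlation), but not without dTAG-NEG replicate 2 (adjusted p = 0.0637) or dTAG-NEG replicate 3 (adjusted p = 0.0502). At a mean of at least 1 CPM the NRF2 targets (adjusted p = 0.0533) and the interferon list (adjusted p = 0.0563) missed, and so did the interferon list with the length or GC smooth (adjusted p = 0.0631 and 0.0550).

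Cytosolic ribosomal protein genes were lower in small steps. Of 43 members 31 fell and 12 did not pass (35 lower adjusted over the list alone), among them RPS19 (-0.40 ± 0.0679) and RPS2 (-0.39 ± 0.0617). Without both replicates 2, 22 fell and the median log2 fold change was -0.12 against -0.21, so the size of the difference rests partly on those libraries. Camera called the list lower (camera adjusted p = 2.87e-06, but adjusted p = 0.478 with an estimated correlation). Ribosome biogenesis and MYC targets went both ways: 5 of 29 rose and 6 fell (5 higher and 6 lower adjusted over the list alone), with NOP16 (0.35 ± 0.0775), ODC1 (0.34 ± 0.0588), POLR1B (0.33 ± 0.0553), RRP12 (0.29 ± 0.0561) and MYC higher and CAD (-0.52 ± 0.0493) lower. Their median log2 fold change was -0.0207 and their mean -0.00113, with a higher camera direction that did not pass (adjusted p = 0.274).

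Matrix genes and markers of other cell types moved too. In the TGF-beta and matrix list 10 of 20 fell and 4 rose (4 higher and 10 lower adjusted over the list alone), with ACTA2 (-1.23 ± 0.130) and TGFB1 (-0.86 ± 0.0881) lower and TGFBI (2.55 ± 0.285), TGFB2 (1.47 ± 0.164), COL12A1 (0.65 ± 0.0791) and SMAD7 (0.37 ± 0.0719) higher. Of 10 fibroblast markers 5 were expressed at a level that could be tested, and all 5 fell (5 lower adjusted over the list alone), COL3A1 from 18.9 ± 2.03 to 1.11 ± 0.496 CPM, COL1A1 from 34.5 ± 2.07 to 17.2 ± 1.23 CPM and PDGFRB from 3.01 ± 0.511 to 1.53 ± 0.223 CPM. Neuronal genes that HEK293 cells express had 6 of 11 members lower and 5 not past (1 higher and 6 lower adjusted over the list alone), with MAP2 from 18.7 ± 2.94 to 11.3 ± 2.27 CPM and ENO2 from 78.8 ± 4.22 to 55.4 ± 3.12 CPM. Camera called the matrix list lower (camera adjusted p = 0.00196, but adjusted p = 0.133 with an estimated correlation), the fibroblast markers (camera adjusted p = 4.39e-06, but adjusted p = 0.0543 with an estimated correlation) and the neuronal list (camera adjusted p = 0.0416, but adjusted p = 0.178 with an estimated correlation). The neuronal list missed without dTAG-NEG replicate 1 (adjusted p = 0.0512), without both replicates 2 (adjusted p = 0.0522) and at a mean of at least 1 CPM (adjusted p = 0.0528). Other cell type markers were rarely expressed, and 4 squamous, 2 leukocyte or blood and 1 hepatocyte or endothelial markers of 10 each could be tested, too few for camera. SFN (-1.27 ± 0.126) and CDH3 (-0.85 ± 0.0815) fell and KRT17 (0.54 ± 0.0993) rose among the squamous markers (1 higher and 2 lower adjusted over the list alone). Of the leukocyte and endothelial markers 0 passed in edgeR, also adjusted over each list alone, 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Without both replicates 2, 1 of 3 hepatocyte or endothelial markers tested fell. CD14 stood at 0.342 ± 0.0882 CPM with dTAG-NEG and 0.652 ± 0.397 CPM with dTAGv-1 and VWF at 1.55 ± 0.0852 CPM with dTAG-NEG and 1.68 ± 0.588 CPM with dTAGv-1. Of 5 non-coding RNAs in the list on RNA quality, the nuclear-retained NEAT1 rose (0.40 ± 0.0458), RN7SL1, the RNA of the cytosolic signal recognition particle, fell (-0.39 ± 0.0556) and 3 did not pass (2 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.803).

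**Figure D3:**
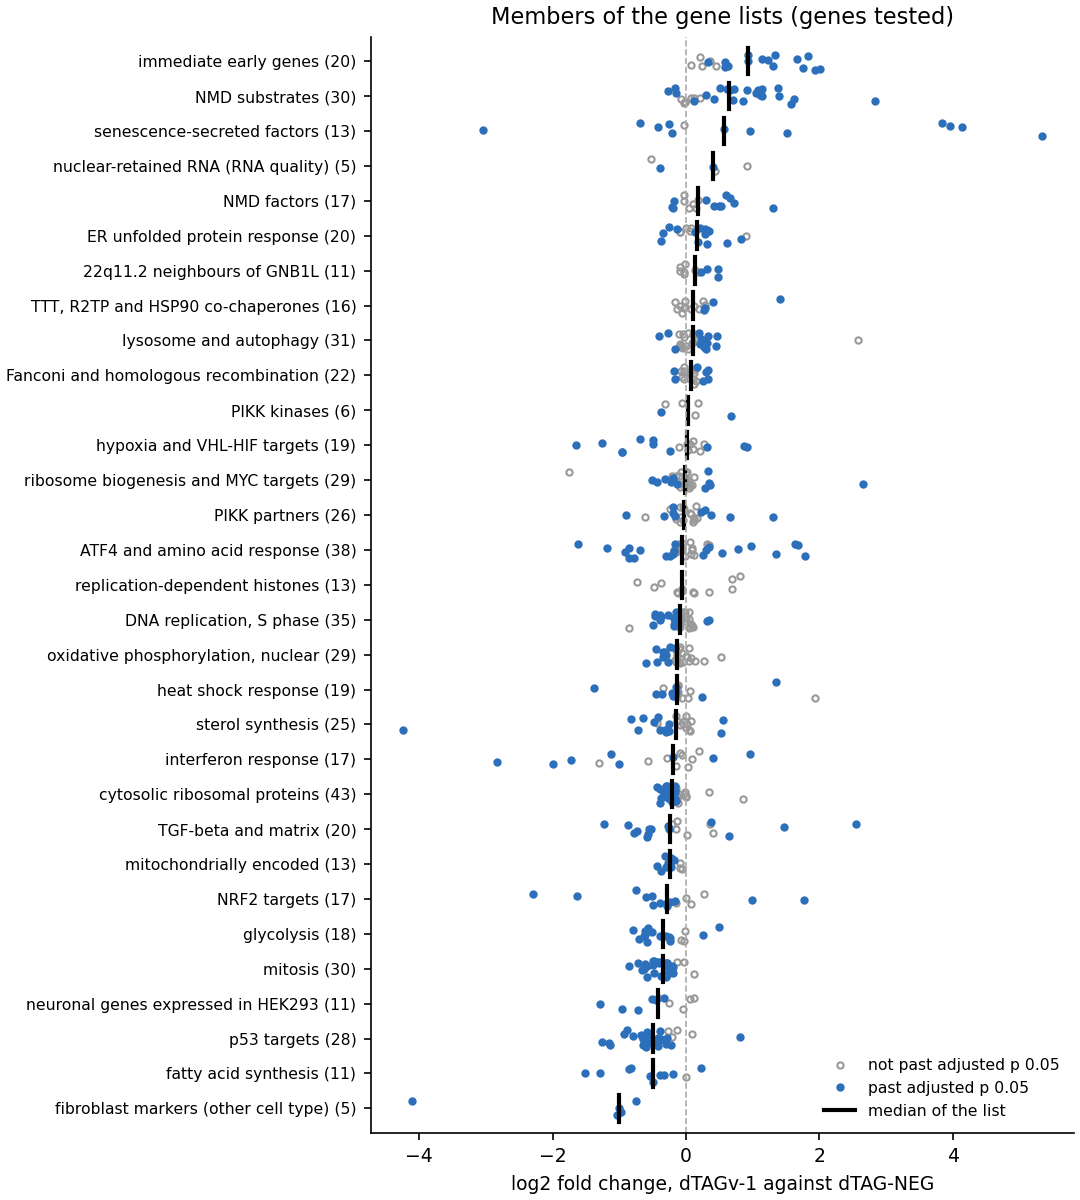
Log2 fold changes, dTAGv-1 against dTAG-NEG, of the tested members of the 31 lists that camera could test, one point per gene, filled blue where it passed an edgeR adjusted p of 0.05 and open grey where it did not, with a bar at each list's median and lists sorted by it. Immediate early genes (median 0.92) and NMD substrates (0.64) lie at the high end, and fibroblast markers (-1.01), fatty acid synthesis (-0.50) and p53 targets (-0.49) at the low end.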

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

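The length and GC smooths, the summed rows and leaving out both replicates 2 were chosen after the results were seen. Of the 133 named genes past the threshold, 104 kept their direction and side of it in every alternative fixed before the data were examined, where tested, and none turned direction. The count of genes past the threshold was 6480 with median-of-ratios scaling, 6485 with library size only, 6510 with no filter, 6312 at 1 CPM, 5988 in DESeq2, 6439 in limma-voom, 5227 to 6415 with a library left out, 7145 and 6737 with the length and GC smooths and 5280 on FPKM. It was 3334 on FPKM with no filter, where 37781 rows were tested. Changes of at least 2-fold numbered 1216 with no filter on the counts, 665 at 1 CPM, 938 in DESeq2, 960 in limma-voom, 951 and 899 with the length and GC smooths and 879 to 990 with a library left out. On FPKM they numbered 414 with a pseudocount of 1, 349 with that pseudocount and no filter and 720 with a pseudocount of 0.1. PIKK mRNAs past the threshold numbered 4 with library size only, no filter or DESeq2. They numbered 3 with median-of-ratios scaling, at 1 CPM or with the GC smooth, with PRKDC added in each. The number was 5 with the length smooth, 1 (SMG1) in each FPKM setting, 1 to 4 with a library left out and 4 without both replicates 2. With the replicate number as a block 5361 genes, 891 at 2-fold, 3 kinases (PRKDC added) and 20 lists passed, but the numbers do not pair the libraries. Deviations of same-numbered libraries correlated across genes at -0.0331, -0.175 and -0.109, and no library correlated best with its own number. GNB1L passed with the GC smooth (0.32, edgeR adjusted p = 0.0441, up to 0.424 elsewhere). Camera called 5 lists with an estimated correlation, 18 to 20 with a library left out and 18 with the length smooth, which lost the interferon and mitochondrially encoded lists, and fry called 24. Of these, 5 were higher in fry alone: PIKK partners, ATF4 (fry adjusted p = 0.00891), ER unfolded protein response (0.00189), lysosome (0.00707) and ribosome biogenesis (0.0330). Fry did not call nuclear oxidative phosphorylation (fry adjusted p = 0.0972). Leaving out at least 1 library ended the calls of ABCC2, ARVCF, CRELD2, HSPA1A, LUM, NEFM, PPAN, PRPH, SESN2, SMG1 and TANGO2. Log2 fold changes of genes not past the threshold also turned direction: H1-2 at 0.0152 with the length smooth, and ranges with libraries left out of -0.190 to 0.0491 for H1-2 and -0.122 to 0.363 for VWF. Summing rows of one symbol ended the calls of ACACA and SESN2. The causes of these differences were not tested. At 22885466 counts or more per library, 3 counts lie at up to 0.131 CPM, so folds of genes near that level are loosely fixed.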

Other observations

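The tests on SMG1 pseudogenes and on non-coding snoRNA host genes were chosen only after the result was seen. Genes outside the NMD lists whose annotated span holds a small nucleolar RNA were counted by type. Host genes that stand in the NMD lists are therefore not in these counts, and whether the small RNA lies in an intron was not tested. Of 26 non-coding host genes 7 rose and 3 fell with dTAGv-1, with a median log2 fold change of 0.21. Of 221 coding host genes 38 rose and 77 fell, with a median of -0.0754 and a camera adjusted p of 0.206. Some coding hosts, such as RPS2, ATP5F1B and HSPA8, are also members of the fixed lists, so these counts partly repeat those of the lists. The difference between the 2 kinds of host genes was not tested.

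SMG1 was higher and ATM lower with dTAGv-1, and all PIKK transcripts are long. After a smooth of each library on transcript length, 2 of the 2 genes stayed past the threshold in the same direction. SMG1 was at 0.75 ± 0.0592 and ATM at -0.32 ± 0.0554 (log2, SE), against 0.67 and -0.38 without it. After a smooth on GC content also 2 of 2 stayed, SMG1 at 0.63 ± 0.148 and ATM at -0.43 ± 0.0830. Each smooth shifted both genes the same way, while their changes were opposite. Such a shift could not bring both to 0, so these results do not decide on either trend as a cause. The 9 rows of SMG1 pseudogenes held 3.93 CPM together with dTAG-NEG and 5.16 CPM with dTAGv-1, too little to supply a rise of 139.7 CPM. Reads that align to both SMG1 and a pseudogene were not analysed here and stay open. So do reads of overlapping genes and all effects of dTAGv-1 other than loss of GNB1L. An effect of GNB1L loss on these mRNAs remains a hypothesis.

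Camera called both NMD lists higher with dTAGv-1, though with an estimated correlation the substrates missed (adjusted p = 0.0543). After the smooths on length and GC, at the preset correlation, the larger of their 2 camera adjusted p was 1.75e-06 and 3.15e-06, which argues against those trends. A candidate explanation is lower NMD activity, since SMG1 protein depends on the PIKK chaperones and several NMD factors are themselves NMD substrates. It was tested on genes outside the NMD lists: 15 coding genes with an exon junction over 50 nt past the stop codon had a median log2 fold change of 0.0861 (5 rose, 2 fell, camera adjusted p = 0.952), at the 79.3 percentile of 10000 random lists of other genes of the same kind and like expression. The non-coding snoRNA hosts, at 0.214, had a camera adjusted p of 0.00426 (adjusted p = 0.261 with an estimated correlation) and the 92.7 percentile. Neither set decides, so lower NMD activity stays open, as does transcription induced by stress, which was not tested.

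The p53 targets were lower with dTAGv-1, and their camera adjusted p was at most 6.74e-18 after the length and GC smooths, which argues against a length or GC trend. A lower activity of the p53 protein, for instance through lower ATM or DNA-PK signalling, may account for the pattern, but protein and phosphorylation were not analysed here. HEK293 lines carry adenovirus proteins that bind p53, which limits what the list can say of other cells.

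The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 6475 genes past the threshold in edgeR and 966 at 2-fold, and 1 of the 10 splits, the real one, gave as many of either. The highest of the other splits gave 0 genes in edgeR and 0 in limma-voom, with 172 to 741 genes below an unadjusted p of 0.05 in edgeR, against 7855 in the real split. Each other split mixes both compounds in each of its groups, so the compound difference enters the spread within them. Few calls were therefore foreseeable there, and the contrast with the real split does not measure chance.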
